A study of Mus musculus with 12 samples.

How the data were processed

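Poly(A) RNA of 12 mouse CD4+ T cell libraries was measured by sequencing. Per the labels, the libraries cover 3 culture conditions (Th1, Th2 and Th17), 2 genotypes (wild type, WT, and NFATc1/ΔS, whose NFATc1 cannot be SUMOylated) and 2 days (2.5 and 3.5), with 1 library for each combination. Per the labels, the Th17 cultures used another medium and less anti-CD3 than the Th1 and Th2 cultures, so cell type and medium cannot be told apart for Th17.

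The authors deposited 1 table per library with 41457 Ensembl genes each. Per the file headers the gene, exon, intron and unique reads are counts, and the values were whole numbers that differed in total between libraries. In every table the gene reads equalled exon plus intron reads. The submitters' notes name the mouse build GRCm38; the aligner and the counting program are not given in the sources used here. Gene positions were read from the deposited tables. The deposited RPKM and TPM values were not used here, because the tests need counts.

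The counts used were the total reads per gene, which include reads that also map elsewhere. They came to between 13417121 and 17774400 per library, of which 78.95 to 81.37% mapped uniquely. Error bars are standard errors from the model and cover counting error and spread between pairs together; the reads carry no molecular identifiers.

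Differential expression was tested with edgeR 4.0.16 in R 4.3.3: TMM normalisation, filterByExpr (min.count 10, min.total.count 15), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. Log2 CPM used a prior count of 2. The genotype effect over 6 pairs used each combination of cell type and day as a block holding 1 WT and 1 NFATc1/ΔS library. The genotype effect in each cell type, and the test of equal effects, came from a single model of all 12 libraries with cell type, day within cell type and genotype within cell type. The day effect used cell type by genotype as blocks, genotype by day used the cell types as replicates, and the cell types were compared with genotype by day as 4 blocks. Signed values are NFATc1/ΔS minus WT, or day 3.5 minus day 2.5. No sample was left out of these fits. These models, the alternatives other than those named as added, the gene lists and the rule for naming genes were chosen before the data were examined.

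The fits to the 8 Th2 and Th17 libraries were added after the results of the 12 had been seen, except that leaving out both pairs of each cell type in turn was already planned for the genotype effect over 6 pairs. They used the same models, filter and thresholds.

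Genes were named by rule. A fixed set of 16 (among them Nfatc1, Nfatc2, Il2, Il2ra, Ifng, Tbx21, Il4, Il13, Gata3, Il17a, Il17f, Foxp3, Prdm1, Bcl6 and Csf2) was followed in every genotype comparison. A few genes are not reported here by name but remain in all tests and counts. Added to these were genes with adjusted p under 0.05, mean log2 CPM of at least 1, the same direction in every pair and a gene symbol that is not a clone, segment or pseudogene name. Of these the largest changes were taken, up to 10 each way over pairs, 7 each way per cell type and 8 each way for day, and the 10 smallest p for the interactions. Where fewer than 5 passed, those of smallest unadjusted p were named and said not to pass. Of each gene list, up to 4 members of smallest unadjusted p are named.

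Gene lists, 27 in all, were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation; fry was run beside it. The lists were Th1, Th2, Th17, regulatory T cell (Treg) and follicular helper (Tfh) genes; IL-2 and STAT5 targets; NFAT targets; the NFAT pathway; the SUMO pathway; co-inhibitory receptors; naive and memory genes; cytokines; chemokines and their receptors; cell cycle; glycolysis; sterol synthesis; BCL2 family and death receptors; interferon response; stress and unfolded protein response; heat shock; markers of B cells, myeloid cells, dendritic cells, CD8 T and NK cells and erythroid cells; mitochondrially encoded genes; and sex-linked genes. The list of co-inhibitory receptors also held genes that are not receptors, such as Il10, Entpd1, Prdm1 and Tox. The sex-linked list had 1 measured member, under the 3 a list test needed, so 26 lists were tested. Several genes belong to more than 1 list (Maf to Th2 and Th17, for example), and lists without the members shared between lineage lists were an alternative.

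Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no read filter, CPM over 1 in enough libraries, no robust fit, unique reads, no blocks, a minimum log2 fold change of 0.5 (glmTreat), each cell type alone, day left out, each genotype alone for the cell types, and each pair or library left out in turn. Exon reads, and for the cell types DESeq2, limma-voom, unique reads, a fit without day and leaving out each library, were added after the data were seen. Other splits were counted by exchanging genotype or day within pairs (32 for 6 pairs, 8 for 4 pairs), and by all 35 ways of splitting the 8 libraries of 2 cell types, fitted without blocks. Positions were tested within 10 Mb of Nfatc1 with Fisher's exact test, and for neighbours within 500 kb against 10000 random gene sets. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6.

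The tests were tested on simulated data in which 200 genes changed, drawn from the means and library sizes of the real libraries. Over 6 pairs (12329 genes) edgeR found 53.7% of 1.5-fold changes, 80.6% of 2-fold and 93.9% of 4-fold changes, and 6.2% of its calls were false. At 1.5-fold limma-voom found 52.2% and DESeq2 56.7% with 15.8% false calls. In the model of each cell type 2-fold changes were found at 34.3% in Th1, 46.3% in Th2 and 43.3% in Th17, and 4-fold changes at 84.8%, 83.3% and 86.4%; false calls came to 8, 11.9 and 19.3%. The test of equal genotype effects found 6% of 2-fold and 69.7% of 4-fold changes, genotype by day 32.8% and 74.2%, and the day effect 70.1% and 93.9%. Among the cell types, 2-fold changes were found at 43.3% for Th1 against Th2, 38.8% for Th1 against Th17 and 65.7% for Th2 against Th17 (12797 genes). On the 8 Th2 and Th17 libraries (12415 genes), 1.5-fold changes were found at 71.6% for the genotype effect over 4 pairs, 68.7% in Th2, 53.7% in Th17, 70.1% for day and 44.8% for genotype by day, and 8.9, 14.2, 11.8, 11.2 and 9.7% of the calls were false. For the genotype effect over these 4 pairs limma-voom found 68.7% of 1.5-fold changes with 9% false calls, and DESeq2 64.2% with 3.7%. The other fits of the 8 libraries were simulated with edgeR alone. The difference of the Th17 and Th2 genotype effects was not simulated. False calls above 5% mean that adjusted p values in these small designs are somewhat too small. In the simulation of 6 pairs, camera with the preset correlation gave a list of 20 genes raised 1.5-fold p = 2.13e-46. It gave 7 of 200 unchanged lists an unadjusted p under 0.05. With an estimated correlation these were 1.93e-05 and 0 lists. The simulated genes were drawn independently of each other, so neither setting was tested on lists of correlated genes.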

Results

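RNA was sequenced from mouse CD4+ T cells to ask how T helper cells respond when the transcription factor NFATc1 can no longer be joined to the small protein SUMO. T cell receptor signals activate NFATc1 through calcineurin. Cells came from spleen and lymph nodes of wild-type (WT) mice and of mice with this change (NFATc1/ΔS). They were cultured toward Th1 cells with IL-12, toward Th2 cells with IL-4 or toward Th17 cells with TGFβ and IL-6, and were collected at day 2.5 or 3.5. There were 12 libraries, 1 for each cell type, genotype and day, so no group had replicates. The WT and NFATc1/ΔS libraries of the same cell type and day formed 6 pairs, and the spread among pairs is the only replicate error. The labels do not say whether libraries came from separate animals or cultures, so p values measure the spread among these libraries. Positions are on GRCm38, the build in the submitters' processing notes.

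Reads on genes came to 14502711 and 14820783 in the libraries labelled Th1 WT day 2.5 and 3.5, and to 15282341 and 16861345 in their NFATc1/ΔS partners. At the same days the Th2 libraries had 14936549 and 14867049 reads (WT) and 15063471 and 13867542 (NFATc1/ΔS). The Th17 libraries had 14160582 and 13417121 (WT) and 13968573 and 17774400 (NFATc1/ΔS). Intron reads made up 2.28 to 4.34% and mitochondrial reads 2.4 to 3.12% of each library. At this depth the spread between pairs, with a biological coefficient of variation of 16% over 6 pairs, outweighed counting error for well-expressed genes.

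Nfatc1 (ENSMUSG00000033016, chromosome 18, 80606205 to 80713071) had 270 and 182.4 CPM (reads scaled to library size) in the libraries labelled Th1 WT day 2.5 and 3.5, and 230.8 and 177.1 in Th1 NFATc1/ΔS. It had 130 and 160 CPM in Th2 WT, 154.9 and 178.1 in Th2 NFATc1/ΔS, 150.7 and 226.8 in Th17 WT, and 171.2 and 251.5 in Th17 NFATc1/ΔS. Its log2 fold change over 6 pairs was 0.08 ± 0.08 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 0.83). Reads were counted per gene and do not show the sequence of the SUMO sites, so Nfatc1 counts check none of the genotype labels. Errors after ± are standard errors, and adjusted p values of genes are from the same edgeR test unless another tool is named.

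The Th2 and the Th17 libraries each lay together, and so did the members of each pair but that of Th1 at day 2.5. The library labelled Th1 WT day 2.5 lay nearer the Th17 libraries, with correlations across genes of 0.955 to 0.977 to them and of 0.938 to 0.949 to the other Th1 libraries. The principal component of largest variance (49.4%) set Th2 apart from Th1, and the next held 21.9%. The log2 differences within the Th1 day 2.5 pair had a standard deviation of 0.77 across genes, and 13.9% of genes (1504 of 10857) differed by more than 1. In the other pairs the standard deviation ran from 0.23 (Th1 day 3.5) to 0.31 (Th17 day 2.5). Each such value describes a single pair of libraries and has no replicate check.

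**Figure D1:**
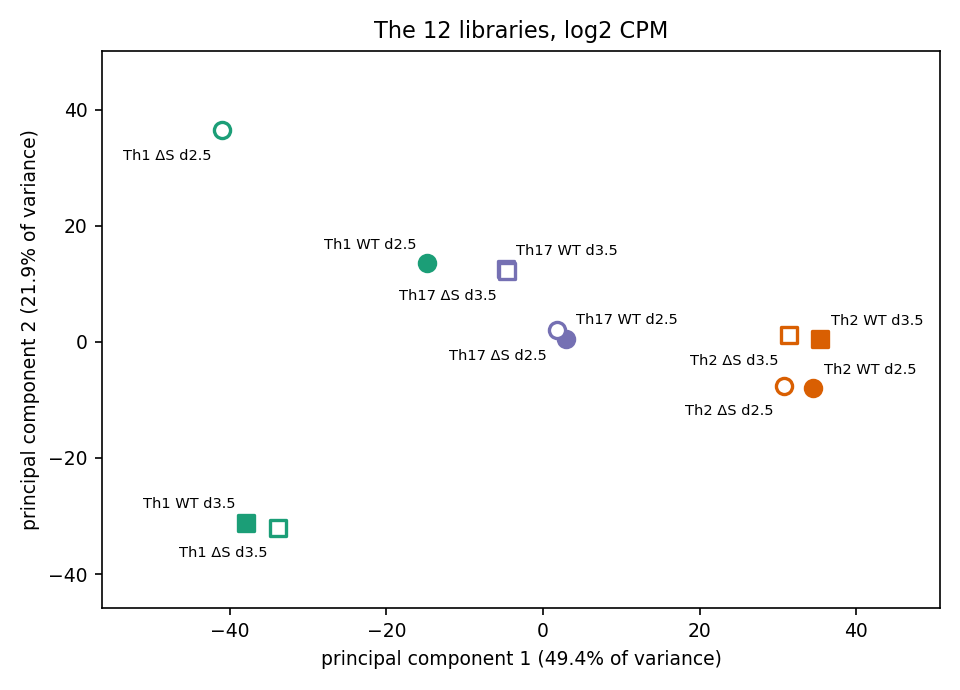
Principal components of log2 CPM of the 12 libraries; each point is a library (filled, WT; open, NFATc1/ΔS; circles, day 2.5; squares, day 3.5; colour, cell type). Component 1 holds 49.4% and component 2 21.9% of the variance, and the libraries of the Th1 day 2.5 pair lie farther apart than those of the other pairs.

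Genes that define each lineage differed between the cell types (n = 4 libraries each). Tbx21, the transcription factor that directs Th1 cells (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), was higher in Th1 than in Th2 by 4.21 ± 0.23 (log2, edgeR adjusted p = 1.9e-05) and than in Th17 by 3.64 ± 0.22 (edgeR adjusted p = 0.000656). Gata3, the factor of Th2 cells (ENSMUSG00000015619, chromosome 2, 9857078 to 9890034), was higher in Th2 than in Th17 by 3.23 ± 0.16 (edgeR adjusted p = 4.35e-05) and lower in Th1 than in Th2 at -3.13 ± 0.16 (edgeR adjusted p = 1.71e-05). The cytokines followed: Ifng was higher in Th1 than in Th2 by 4.57 ± 0.61 (edgeR adjusted p = 0.00101), and Il17f was lower in Th1 than in Th17 at -6.57 ± 0.65 (edgeR adjusted p = 0.00195).

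Of 21 measured Th1 genes, 13 were higher and 1 lower in Th1 than in Th2, with Fasl at 3.86 ± 0.16 (edgeR adjusted p = 9.09e-06) and Il12rb2 at 2.78 ± 0.22 (edgeR adjusted p = 8.98e-05) among the clearest, and 7 did not pass. Against Th17, 10 were higher and 11 did not pass (12 higher adjusted over the list alone). Of 17 Th2 genes, 16 were higher in Th2 than in Th1, and 16 were higher in Th2 than in Th17, among them Epas1 (4.91) and Il4ra (1.41). Of 18 Th17 genes, 10 were lower in Th1 than in Th17 (14 adjusted over the list alone), with Ccr6 at -3.43 ± 0.32 (edgeR adjusted p = 0.00194). Between Th2 and Th17, 6 Th17 genes such as Ccr6 (-4.86) were higher in Th17, but 4 were higher in Th2, among them Batf (2.27). Markers of other cells differed as well. Of 9 B cell markers 9 were lower in Th1 than in Th2 (median -3.74), 5 were lower in Th1 than in Th17 (-1.94) and 4 were higher in Th2 than in Th17 (1.74). Of 7 dendritic cell markers these counts were 6 (-3.22), 2 (-2.09) and 3 (1.38). In all, edgeR counted 3656 genes for Th1 against Th2 (1867 higher, 1789 lower in Th1), 611 for Th1 against Th17 (249 and 362) and 1539 for Th2 against Th17 (814 and 725) of 12797 tested. For Th1 against Th2 the balance depended on scaling and tool, with 1644 higher and 1940 lower by RLE size factors, 2069 and 2308 by DESeq2, and 1753 and 1926 by limma-voom. With NFATc1/ΔS libraries alone edgeR counted 0 for each, and medium and cell type cannot be told apart in contrasts with Th17.

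Over all 6 pairs no gene differed between NFATc1/ΔS and WT beyond the spread among pairs. Slamf6, a receptor that T and B cells use to bind each other, came closest on the higher side among genes that met the naming rule. Its value was 0.94 ± 0.13 (edgeR adjusted p = 0.391), higher in 6 of 6 pairs as the rule requires. Tmtc2 came closest on the lower side (-0.77 ± 0.11, edgeR adjusted p = 0.391). The smallest adjusted p of all, 0.0653, was that of Gm21887, whose clone-type symbol lies outside the rule and which was picked out after its value was seen. The other genes of smallest p, which did not pass, were Sh3gl3, Wdr62, Cln3 and Btla on the higher side and Ermn, Asns, Ifitm2 and Tmem163 on the lower side. Of the 16 genes followed throughout none passed, with edgeR adjusted p between 0.823 and 0.968. Il17f was not tested, because the read filter left it out. It had 8.1 to 60.5 CPM in the Th17 libraries and at most 1.2 CPM in the others. edgeR counted 0 of 12329 genes (716 at an unadjusted p under 0.05), limma-voom 1 and DESeq2 21. Without both Th1 pairs the edgeR count was 264, and without the Th1 day 2.5 pair alone it was 23.

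As lists, 3 of 26 were higher and 10 lower in NFATc1/ΔS over 6 pairs by camera with a preset correlation. Higher were cell cycle (camera adjusted p = 2.82e-09), mitochondrially encoded (0.00256) and Tfh genes (0.00593). Lower were glycolysis (camera adjusted p = 1.75e-07), Th17 (5.35e-06), sterol synthesis (6.29e-06), IL-2 and STAT5 targets (0.00256), CD8 T and NK markers (0.00256), stress response (0.00565), Treg (0.0119), cytokines (0.0214), Th2 (0.0296) and dendritic cell markers (0.0332). With an estimated correlation none of these held (adjusted p = 0.234 with an estimated correlation, and 0.474 for the mitochondrial list). No member of any list passed over all genes. Adjusted over the list alone, 3 Treg genes and 3 genes of the co-inhibitory list were lower and 1 of each list higher. In the same way 2 Tfh genes and 1 naive and memory gene were higher, and 2 sterol synthesis genes, 1 stress response gene and 1 CD8 T and NK marker were lower. The other 13 lists did not pass (camera adjusted p between 0.216 and 0.957), NFAT targets (0.903), the NFAT pathway (0.325) and the SUMO pathway (0.362) among them. No list had a median, mean and test of opposite sign.

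In the 4 Th2 and Th17 pairs, fitted without Th1, NFATc1/ΔS cells had lower levels of some cytokine genes, and most of the 26 measured did not pass. Il13, a Th2 effector cytokine (ENSMUSG00000020383, chromosome 11, 53631324 to 53634702), was lower at -0.84 ± 0.09 (edgeR adjusted p = 0.000167, lower in 4 of 4 pairs). Il17f (ENSMUSG00000041872, chromosome 1, 20777146 to 20790617) was lower at -1.65 ± 0.22 (edgeR adjusted p = 0.00604, lower in 3 of 4 pairs), and its neighbour Il17a at -1.13 ± 0.21 (edgeR adjusted p = 0.0137). Maf, a factor that promotes IL-4 and IL-10 (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794), was lower at -0.98 ± 0.07 (edgeR adjusted p = 9.78e-07), and the IL-2 receptor gene Il2ra at -0.31 ± 0.08 (edgeR adjusted p = 0.0492). Not every alternative kept these calls: without the Th2 day 2.5, Th17 day 2.5 or Th17 day 3.5 pair the edgeR adjusted p of Il2ra was 0.243, 0.111 or 0.281 and that of Il17a 0.0773, 0.0863 or 0.122. Il17f had 0.0619 without the Th2 day 2.5 pair and 0.326 by DESeq2, and Il2ra 0.0525 with RLE size factors and 0.0695 without the robust fit. Il13 had 129.6 and 406.3 CPM at days 2.5 and 3.5 in Th2 WT and 81.5 and 241.5 in Th2 NFATc1/ΔS. Il17f had 60.5 and 20.8 CPM in Th17 WT and 14.7 and 8.1 in Th17 NFATc1/ΔS. In the Th2 libraries Il17f had only 0.3 to 1.2 CPM and Il17a 1.1 to 2.3 CPM.

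Among the genes named for these 4 pairs, Gdpd3 fell and Apobr rose the most. Gdpd3, a lysophospholipase D gene (ENSMUSG00000030703, chromosome 7, 126766334 to 126775649), was lower at -6.36 ± 0.46 (edgeR adjusted p = 0.0208). It had 92.8 and 65 CPM in Th2 WT and 42.8 and 26.2 in Th17 WT, against 0.2 and 0.7 in Th2 NFATc1/ΔS and 0.5 and 1 in Th17 NFATc1/ΔS. Apobr, a lipoprotein receptor gene of the same chromosome (ENSMUSG00000042759, 126584942 to 126589112), was higher by 3.23 ± 0.21 (edgeR adjusted p = 6.99e-07). Cd93, which codes for a surface glycoprotein (ENSMUSG00000027435, chromosome 2, 148436640 to 148443563), was lower at -2.20 ± 0.14 (edgeR adjusted p = 8.65e-07), with 29.7 and 29.5 CPM in Th2 WT against 8.3 and 5.4 in Th2 NFATc1/ΔS. Slamf6 (ENSMUSG00000015314, chromosome 1, 171917515 to 171953170) was higher by 1.09 ± 0.10 (edgeR adjusted p = 1.45e-05). The gene of the cytotoxic protease granzyme A, Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981), was lower at -1.48 ± 0.20 (edgeR adjusted p = 0.0391). Also among the largest rises were Setbp1 (1.31), Slc14a1 (1.25), Tnfrsf26 (1.06), Mid1 (1.05), Pdlim4 (0.99), Sh3gl3 (0.98), Igflr1 (0.90) and Vipr1 (0.89). Among the largest falls were Bpifa2 (-3.27), Gpr141 (-1.56), Ermn (-1.32), Ctla2b (-1.16), Gpnmb (-1.15) and Upp1 (-1.13). Without the Th2 day 2.5 or the Th17 day 3.5 pair Gzma did not pass (edgeR adjusted p = 0.247 or 0.134), nor Gdpd3 without the Th2 day 3.5 or the Th17 day 2.5 pair (0.0926 or 0.124). Gpr141 (0.116), Vipr1 (0.0739) and Igflr1 (0.0687) did not without the Th17 day 3.5 pair, and Igflr1 without either day 2.5 pair (0.128 for Th2, 0.101 for Th17). Igflr1 passed in 7 of 11 alternatives. Setbp1 and Slc14a1 lie within 10 Mb of Nfatc1, and Igflr1 (4.3% unique reads) and Ctla2b (16.3%) are uncertain because most of their reads also map elsewhere.

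**Figure D2:**
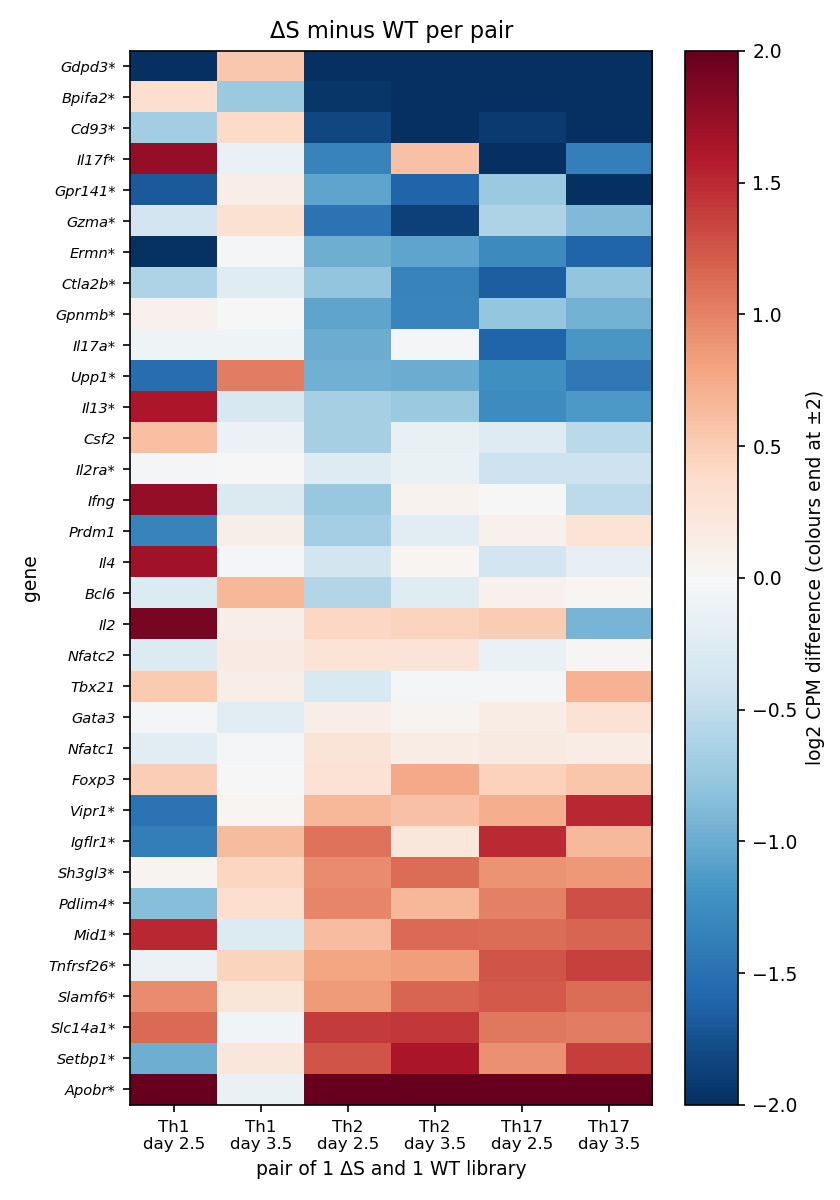
Log2 CPM difference, NFATc1/ΔS minus WT, of genes named in the text for the comparison over 4 Th2 and Th17 pairs, with a column for each of the 6 pairs and a star for edgeR adjusted p under 0.05. Gdpd3 and Cd93 are lower and Apobr and Slamf6 higher in each of the 4 Th2 and Th17 pairs, as the naming rule requires. The colours end at 2 and -2.

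Counted over the 12415 genes tested in these 8 libraries, 93 were higher and 171 lower in NFATc1/ΔS (edgeR, 264 in all). Of the genes followed throughout, Foxp3, the Treg factor, was at 0.54 ± 0.16 and did not pass (edgeR adjusted p = 0.0987; 20.2% unique reads), nor did Nfatc1 (0.18 ± 0.06, edgeR adjusted p = 0.132). Nfatc2, Il2, Ifng, Tbx21, Il4, Gata3, Prdm1, Bcl6 and Csf2 did not pass either, with edgeR adjusted p between 0.312 (Gata3) and 0.912 (Il2). The biological coefficient of variation in these libraries was 7.9%.

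Th17 genes stood out among the lists in these 4 pairs. Of 18 measured, 6 were lower and 12 did not pass (10 lower adjusted over the list alone). The list median was -0.33 (camera adjusted p = 2.92e-11; adjusted p = 0.118 with an estimated correlation). Of 17 Th2 genes, 4 were lower (6 adjusted over the list alone), namely Maf, Il13, Il24 (-0.73 ± 0.09) and Il5 (-1.06 ± 0.15). The Th2 list was lower (camera adjusted p = 4.04e-05; adjusted p = 0.227 with an estimated correlation). Of 26 cytokines 6 were lower (8 lower and 2 higher adjusted over the list alone). The cytokine list had camera adjusted p = 1.29e-06 (adjusted p = 0.272 with an estimated correlation). Of 19 Treg genes 3 were lower, Ctla4 (-0.53), Entpd1 (-0.68) and Il2ra, and adjusted over the list alone 6 were lower and 2 higher. The Treg list had camera adjusted p = 0.0372 (adjusted p = 0.283 with an estimated correlation). Of 20 Th1 genes Il12rb2 was lower (-0.54), as it was adjusted over the list alone, and the list was lower (camera adjusted p = 0.0337; adjusted p = 0.37 with an estimated correlation). Of 24 IL-2 and STAT5 targets 3 were lower (3 lower and 1 higher adjusted over the list alone), and the list was lower (camera adjusted p = 0.0133). It had adjusted p = 0.283 with an estimated correlation. Of 18 stress response genes 2 were lower, Asns (-0.49) and Pdia6 (-0.28), and adjusted over the list alone 9 were lower and 1 higher. The stress list had camera adjusted p = 2.73e-06 (adjusted p = 0.274 with an estimated correlation).

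Naive and memory genes were higher as a list (camera adjusted p = 0.000121; adjusted p = 0.283 with an estimated correlation). Of 16, Actn1 (0.41) and Txk (0.54) were higher and Il7r (-0.38) was lower (7 higher and 1 lower adjusted over the list alone). Cell cycle genes were higher as a list with a median of 0.15, though none of 26 passed over all genes (6 higher adjusted over the list alone). Their camera adjusted p was 3.89e-09 (adjusted p = 0.283 with an estimated correlation). Of 17 Tfh genes Slamf6 passed (5 higher adjusted over the list alone; camera adjusted p = 0.00208; adjusted p = 0.274 with an estimated correlation). Lower as lists were glycolysis genes (camera adjusted p = 0.000308), sterol synthesis genes (4.04e-05, with Dhcr7 at -0.41) and CD8 T and NK markers (0.000889, with Gzma). The mitochondrially encoded list was higher (camera adjusted p = 0.0148). With an estimated correlation these adjusted p values were 0.381, 0.381, 0.272 and 0.604.

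Of 25 NFAT targets, 3 were higher, the early response factors Egr1 (0.43 ± 0.06, edgeR adjusted p = 0.00119), Nr4a3 (0.46 ± 0.07, edgeR adjusted p = 0.00167) and Egr2 (0.35 ± 0.08, edgeR adjusted p = 0.0337), and Il13 was lower (6 higher and 3 lower adjusted over the list alone). The list itself did not pass (camera adjusted p = 0.564), and its median and mean were below 0 while the test pointed up. The remaining lists did not pass: NFAT pathway (camera adjusted p = 0.0551), B cell markers (0.0551, with Ebf1 lower at -0.90), chemokines (0.0844), BCL2 family (0.102), co-inhibitory receptors (0.143, with Ctla4 and Entpd1 lower), dendritic cell markers (0.241), interferon response (0.441), erythroid markers (0.759), SUMO pathway (0.783), heat shock (0.789) and myeloid markers (0.896). Median, mean and test also differed in sign for the interferon and erythroid lists. Of the sex-linked genes Xist alone was measured, and it did not differ by genotype (0.14 ± 0.29, edgeR adjusted p = 0.904).

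In Th2 cells (2 pairs, fitted within the 8 libraries), some genes of cytotoxic and Th1-type function were lower in NFATc1/ΔS, as were some Th2 cytokines. Gzma was lower at -1.67 ± 0.10 (edgeR adjusted p = 4.33e-06), with 180.8 and 183.4 CPM in WT against 65.1 and 50.4, and Il10, an anti-inflammatory cytokine gene (ENSMUSG00000016529, chromosome 1, 131019845 to 131024974), at -1.64 ± 0.19 (edgeR adjusted p = 0.00492). Of 20 Th1 genes 4 were lower (5 adjusted over the list alone), among them Gzmb (-0.86), Il12rb2 (-0.65) and Nkg7 (-0.88). The Th1 list was lower (camera adjusted p = 1.47e-05; adjusted p = 0.358 with an estimated correlation). Of 17 Th2 genes 6 were lower (8 adjusted over the list alone), Maf (-0.92), Il13 (-0.72 ± 0.08, edgeR adjusted p = 0.000346), Il5 (-1.06) and Il24 (-0.55) with the smallest p, while Il4 did not pass (-0.15 ± 0.12, edgeR adjusted p = 0.743). The Th2 list had camera adjusted p = 5.65e-06 (adjusted p = 0.358 with an estimated correlation). Of 5 CD8 T and NK markers 3 were lower, Gzma, Klrc1 (-1.17) and Klrk1 (-1.53), as adjusted over the list alone. These markers had camera adjusted p = 3.73e-05 (adjusted p = 0.358 with an estimated correlation). Of 14 genes of the co-inhibitory list, Il10, Ctla4 (-0.55), Tigit (-0.57) and Entpd1 (-0.82) were lower. The gene Tox, which is not a receptor, was higher. Adjusted over the list alone the counts were the same. The list had camera adjusted p = 0.00116 (adjusted p = 0.358 with an estimated correlation).

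The other lists that passed in Th2 were cell cycle (camera adjusted p = 5.65e-06), erythroid markers (0.00674) and mitochondrially encoded genes (0.0173), all higher. Lower were stress response (7.06e-05), glycolysis (7.25e-05), Th17 (0.00116), cytokines (0.00359), Treg (0.0242), B cell markers (0.0277) and chemokines (0.0325). With an estimated correlation none of these passed (adjusted p = 0.358 to 0.608 with an estimated correlation).

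Also higher in Th2 were Apobr (3.11), Slc14a1 (1.49), Setbp1 (1.45), Tox (1.24 ± 0.26, edgeR adjusted p = 0.0365) and Sh3gl3 (1.04); Tox did not pass on unique reads (1.14, edgeR adjusted p = 0.0859). Ptger1 (1.81, 0.1% unique reads) and Hbb-bs (1.55, 29.7% unique reads) passed as well and are uncertain for that reason. Gdpd3 (-7.46), Bpifa2 (-2.31), Cd93 (-2.14) and Slc17a6 (-1.45) were lower. Without the Th2 day 2.5 pair Klrk1 (edgeR adjusted p = 0.136), Slc14a1 (0.147), Tox (0.393) and Hbb-bs (0.603) did not pass, without the Th2 day 3.5 pair Klrk1 (0.182), Slc14a1 (0.0864) and Sh3gl3 (0.0615) did not, and without the Th17 day 2.5 pair Il10 (0.0508) did not. DESeq2 did not call Klrk1, Slc14a1, Setbp1, Tox, Sh3gl3, Hbb-bs or Ptger1. Of 12 alternatives, Tox and Klrk1 each passed in 7, Slc14a1 in 8 and Hbb-bs in 9. edgeR counted 30 genes higher and 98 lower in Th2 (128 in all; DESeq2 53).

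In Th17 cells (2 pairs, fitted within the 8 libraries), some genes of the Th17 programme were lower in NFATc1/ΔS and some genes of naive cells higher, though most of either list did not pass. Il17a (ENSMUSG00000025929, chromosome 1, 20730905 to 20734496) was lower at -1.40 ± 0.20 (edgeR adjusted p = 0.00208), Il17f at -1.73 ± 0.20 (edgeR adjusted p = 0.00234) and Il13 at -1.22 ± 0.14 (edgeR adjusted p = 0.000297), each in both pairs. Of 18 Th17 genes 5 were lower (10 adjusted over the list alone), among them Maf (-1.06) and Ltb4r1 (-1). The list median was -0.47 (camera adjusted p = 2.22e-12; adjusted p = 0.447 with an estimated correlation). Of 16 naive and memory genes 5 were higher (11 higher and 2 lower adjusted over the list alone), among them the stem-like T cell factor Tcf7 (0.46, 19.7% unique reads), Actn1 (0.43) and Klf2 (0.74). This list had camera adjusted p = 4.38e-08 (adjusted p = 0.447 with an estimated correlation). Of 17 Tfh genes Slamf6 (1.17), Tcf7 and Pou2af1 (0.86) were higher (5 adjusted over the list alone), with camera adjusted p = 2.44e-05 for the list (adjusted p = 0.447 with an estimated correlation). Of 17 Th2 genes Maf, Il24 (-0.95), Il13 and Ccr4 (-0.54) were lower, 4 also adjusted over the list alone. The Th2 list had camera adjusted p = 0.012 (adjusted p = 0.462 with an estimated correlation). The other lists that passed in Th17 were cell cycle (camera adjusted p = 3.86e-06) and the BCL2 family (0.035), higher, and sterol synthesis (9.26e-07), cytokines (6.72e-06), stress response (0.000104) and IL-2 and STAT5 targets (0.019), lower. With an estimated correlation none of these passed (adjusted p = 0.447 to 0.48 with an estimated correlation).

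The largest other rises in Th17 were Olfr56 (4.11), Apobr (3.50), Capn11 (3.03 ± 0.23, edgeR adjusted p = 7.75e-06), Fmo1 (2.17, 0.6% unique reads and so uncertain), Ppic (1.85), Akap6 (1.64) and Slc13a3 (1.40). The largest falls were Gdpd3 (-5.36), Bpifa2 (-3.90), Cd93 (-2.32), Gpr141 (-1.61), Akr1c18 (-1.56), Aldh1l2 (-1.48) and Ermn (-1.45). Without the Th17 day 2.5 pair Akap6 (edgeR adjusted p = 0.419), Aldh1l2 (0.0947) and Il17a (0.0698) did not pass, and without the Th17 day 3.5 pair Akap6 (0.113), Gpr141 (0.715) and Ppic (0.0645) did not. DESeq2 did not call Akap6, Gpr141 or Aldh1l2. Akap6 passed in 6 of 11 alternatives and Gpr141 in 9 of 12. edgeR counted 92 genes higher and 130 lower in Th17 (222 in all; DESeq2 94).

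Some of these effects differed between Th17 and Th2 when the difference itself was tested. The protease gene Capn11 rose in Th17 and not in Th2 (difference 3.02 ± 0.28, edgeR adjusted p = 0.000314), with 0.8 and 2.1 CPM in Th17 WT against 9.1 and 14.3 in Th17 NFATc1/ΔS. The effect was more positive in Th17 than in Th2 for the cytotoxic and Th1-type genes Prf1 (1.47 ± 0.21, edgeR adjusted p = 0.0107, but 0.0911 by DESeq2), Gzmb (0.82, edgeR adjusted p = 0.0219) and Nkg7 (1.06, edgeR adjusted p = 0.0472). It was also more positive for Tigit (0.91, edgeR adjusted p = 0.0219) and Pou2af1 (1.23, edgeR adjusted p = 0.0247), and more negative for Batf3 (-1.42 ± 0.17, edgeR adjusted p = 0.00266). No difference passed for Il17a (edgeR adjusted p = 0.695), Il17f (0.929), Il13 (0.46), Il10 (0.751), Gzma (0.135), Tcf7 (0.538) or Klf2 (0.776). These effects are therefore not shown to belong to either cell type. In the Th2 libraries Il17f had only 0.3 to 1.2 CPM and Il17a 1.1 to 2.3 CPM. At such levels a difference could hardly be detected, so for Il17a and Il17f the test does not show a shared effect. edgeR counted 28 genes with a more positive and 9 with a more negative effect in Th17 (37 in all), limma-voom 16 and DESeq2 14.

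When all 12 libraries were fitted together, no gene passed for any cell type. Th1 cells had 0 genes (edgeR; 643 at an unadjusted p under 0.05; DESeq2 1, limma-voom 0). Icam2, Ddx51, Dgcr8, Marcksl1 and Mgat2 ranked highest on the higher side and Capn11, Slco1a6, Vill, Ifitm2 and Itgb3 on the lower side (edgeR adjusted p = 0.573 for each, not passing). The Th1 pairs disagreed: Ifng differed by 1.76 at day 2.5 and -0.29 at day 3.5, Il2 by 1.90 and 0.11, and Il4 by 1.68 and -0.02. In Th1, 4 lists passed: cell cycle (camera adjusted p = 0.0057), mitochondrially encoded (0.0268) and heat shock genes (0.0409) up and glycolysis (0.000179) down, with an adjusted p of at least 0.55 with an estimated correlation for each. Without the Th1 day 2.5 pair the cell cycle list reversed and pointed down (camera adjusted p = 0.0109), and 1 of these 4 lists was among those that passed. Th2 had 0 genes in this fit (edgeR; 274 at an unadjusted p under 0.05; DESeq2 10, limma-voom 0). Th17 had 0 (edgeR; 356 at an unadjusted p under 0.05; DESeq2 15, limma-voom 0), and the test of equal effects 0 (edgeR; 271 at an unadjusted p under 0.05; DESeq2 3, limma-voom 0). Without the Th1 day 3.5 pair the Th1 count was 5133, which then rested on the day 2.5 pair alone.

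**Figure D3:**
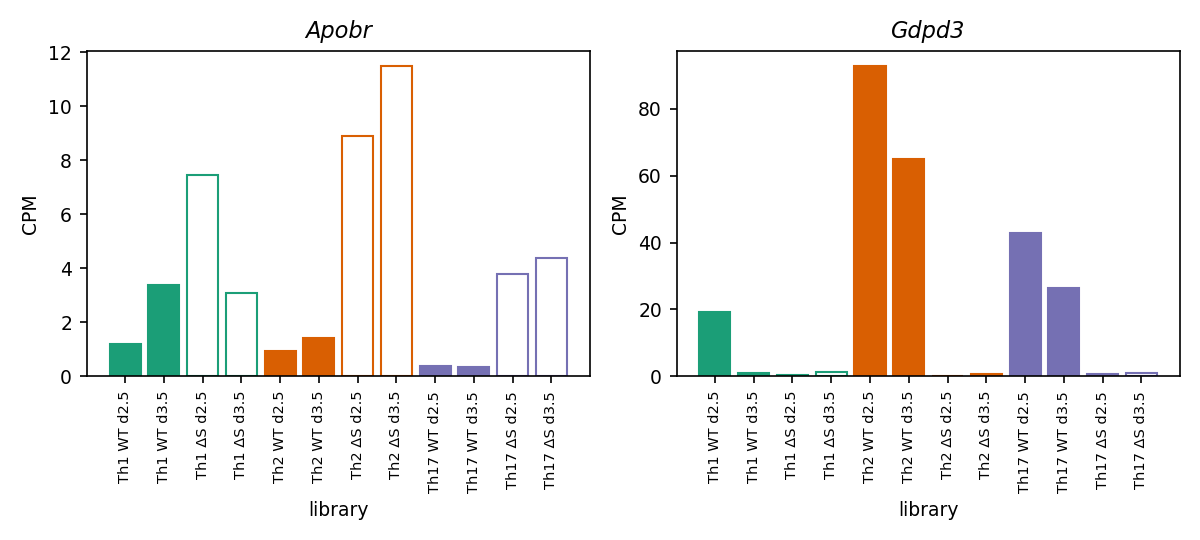
CPM of Apobr and Gdpd3 in each of the 12 libraries (filled bars, WT; open bars, NFATc1/ΔS; colour, cell type). The library labelled Th1 WT day 3.5 has 0.8 CPM of Gdpd3 and 3.4 of Apobr, where the other WT libraries have at least 19.2 and at most 1.4.

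From day 2.5 to day 3.5, Th2 and Th17 cells raised cell cycle genes and lowered glycolysis genes. Of 26 cell cycle genes 24 rose (25 adjusted over the list alone), such as Ccnb1 (0.65 ± 0.07, edgeR adjusted p = 6.98e-05) and Mki67 (0.67 ± 0.10, edgeR adjusted p = 0.00052); the list rose (camera adjusted p = 2.31e-09; adjusted p = 0.857 with an estimated correlation). Of 19 glycolysis genes 17 fell, such as Slc2a3 (-0.81 ± 0.07, edgeR adjusted p = 2.01e-05) and Gapdh (-0.85 ± 0.07, edgeR adjusted p = 2.62e-05). The glycolysis list fell with camera adjusted p = 8.26e-10 (adjusted p = 0.857 with an estimated correlation). Of 17 Th2 genes 6 rose and 2 fell, as adjusted over the list alone, with Il13 (1.47), Il4 (1.06) and Il5 (1.49) rising. The Th2 list rose with camera adjusted p = 0.0497 (adjusted p = 0.962 with an estimated correlation). Of 16 naive and memory genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), such as Ccr7 (-1.04). This list fell (camera adjusted p = 0.0139), as did the erythroid markers (camera adjusted p = 0.0497), each with adjusted p = 0.857 with an estimated correlation. Nfatc1 itself rose by 0.43 ± 0.08 (edgeR adjusted p = 0.00169).

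The largest rises by day in these libraries were Slc17a6 (2.34 ± 0.13, edgeR adjusted p = 4.31e-06), Akr1c18 (2.19), Muc13 (2.16), Ptprv (1.67), Jrk (1.6), S100a6 (1.6), Dlg2 (1.5) and Spp1 (1.49). The largest falls were Hbb-bs (-3.46 ± 0.21, edgeR adjusted p = 5.81e-06), Hba-a2 (-2.65), the growth factor receptor gene Kit (-2.02), Adm (-1.96), Fam183b (-1.95), Asb16 (-1.82), Bpifa2 (-1.79) and Proser2 (-1.79); most reads of the globin genes and of Adm also map elsewhere. Over all 6 day pairs, edgeR counted 0 genes (1333 at an unadjusted p under 0.05; limma-voom 0, DESeq2 143), and over the 4 Th2 and Th17 day pairs 5022 (2582 up, 2440 down). Over 6 pairs the genes of smallest p, which did not pass, were Gpr83, Fgf2, Hivep3, Tube1 and Hap1 on the rising side and Snhg6, Plac8, Eno1, Bpifa2 and Pde3b on the falling side.

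Th1 libraries ran against this course. Slopes were taken over the 4737 genes with a day effect in Th2 and Th17 cells and a mean log2 CPM of at least 1 over the 12 libraries. The Th1 day change had a slope of -1.11 on that effect in NFATc1/ΔS and -0.25 in WT, where Th2 gave 0.96 and 0.94 and Th17 1 and 1.06. In the fit of all 12 libraries edgeR counted 673 genes for day in Th1 (325 up, 348 down). In that fit it counted 0 in Th2 (2310 at an unadjusted p under 0.05) and 0 in Th17 (2697). Over 6 day pairs 7 lists passed. Cell cycle genes (camera adjusted p = 0.000221) went up, and Th1 (0.000221), CD8 T and NK markers (0.00103), heat shock (0.00581), glycolysis (0.0142), chemokines (0.0326) and mitochondrially encoded genes (0.0331) down. With an estimated correlation their adjusted p was 0.507 for the Th1 genes and the CD8 T and NK markers and 0.633 for the others.

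**Figure D4:**
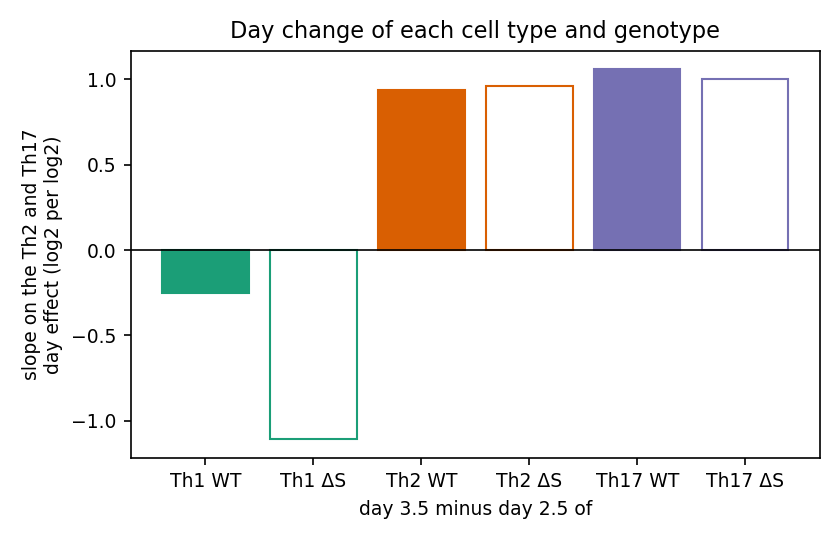
Slope of each cell type's and genotype's day change on the day effect of the Th2 and Th17 libraries, over 4737 genes; each bar is 1 pair of libraries (filled, WT; open, NFATc1/ΔS). The Th1 bars stand at -0.25 (WT) and -1.11 (NFATc1/ΔS), and the Th2 and Th17 libraries, from which the genes were chosen, between 0.94 and 1.06.

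Few genes had a genotype effect that changed with the day. In the 8 Th2 and Th17 libraries the genotype effect was more positive at day 3.5 for Map3k8, a kinase of inflammatory signalling (1.07 ± 0.13, edgeR adjusted p = 0.000825). The same held for the noncoding RNA Malat1 (0.82 ± 0.11, edgeR adjusted p = 0.00169), Ccnl1 (0.99 ± 0.14, edgeR adjusted p = 0.00222) and Ikbke (0.84, edgeR adjusted p = 0.00297). It was more negative for the histone gene Hist1h2ap (-1.71 ± 0.15, edgeR adjusted p = 0.000825; 14.9% unique reads, so uncertain), Cox5b (-0.75, edgeR adjusted p = 0.00251) and Scand1 (-1.28, edgeR adjusted p = 0.00936, but 0.0713 by limma-voom and 0.0754 without the robust fit). edgeR counted 19 genes more positive and 14 more negative (33 in all; limma-voom 12, DESeq2 11). Over all 12 libraries it counted 0 (919 at an unadjusted p under 0.05; limma-voom 0, DESeq2 2). Map3k8 (1.13), Paxbp1 (0.97), Rgs1 (0.56), Vps54 (0.65) and Malat1 (0.91) were among those of smallest p, none passing (edgeR adjusted p = 0.618 for each). At day 3.5 intron reads made up 3.98 and 4.16% of the Th2 and Th17 NFATc1/ΔS libraries against 2.93 and 3.28% in WT, and at day 2.5 2.32 and 2.89% against 2.28 and 3.43%. On exon reads Malat1 (0.86), Ccnl1 (1), Map3k8 (0.93) and Ikbke (0.84) still passed, and by DESeq2 Ikbke did not (adjusted p = 0.14). Counting exon reads leaves out intron reads but keeps the exon reads of unspliced RNA. It therefore cannot decide whether these calls follow the share of unspliced RNA. Each count here rests on 3 pairs or fewer per day.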

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

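The tests of Th1 sample labels and of Th17 RNA, the test of genes near Nfatc1, and the fits of the 8 Th2 and Th17 libraries, except the genotype effect without both Th1 pairs, were chosen only after the results they test had been seen; the tests of unique reads, of neighbouring genes and of other splits were written before their results were seen.

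In 30 groups of 6 values tested for a far value, 4 had one, each time the Th1 day 2.5 pair. The groups held libraries of a genotype, WT and NFATc1/ΔS pairs, or day slopes, and the 4 all came from groups of pairs. Chance alone gives about 1 in 20 groups, and groups that share the same pairs or libraries are not independent. In the Th1 day 2.5 pair the standard deviation of the log2 differences across genes was 0.77, where the next highest pair had 0.31. Its NFATc1/ΔS minus WT difference was 1.76 for Ifng (next highest pair 0.07), 1.68 for Il4 (next 0.04) and 1.61 for Il13 (next -0.32).

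Genotype effects differed between Th17 and Th2 cells, by a test of the difference, for some of the named genes. The difference (Th17 minus Th2, log2) was positive for Fmo1 (3.17), Capn11 (3.02), Sgip1 (1.53), Prf1 (1.47), Il1r2 (0.99) and Itgb3 (0.79), and negative for Batf3 (-1.42), Akr1c18 (-1.10) and Dennd5a (-0.81). Without the Th17 day 3.5 pair Akr1c18 (edgeR adjusted p = 0.102) and Itgb3 (0.0584) did not pass, nor did Prf1 by DESeq2 (0.0911) or Sgip1 on unique reads (0.0698). Between the days, by the same kind of test, the effect was more positive at day 3.5 for Map3k8 (1.07), Ccnl1 (0.99), Lilr4b (0.89), Ikbke (0.84), Mapk8ip3 (0.83), Malat1 (0.82) and Srsf5 (0.64). It was more negative for Hist1h2ap (-1.71), Scand1 (-1.28) and Cox5b (-0.75). Lilr4b did not pass without the Th2 day 2.5 or 3.5 pair (edgeR adjusted p = 0.322 or 0.104) or on unique reads (0.506), nor did Srsf5 (0.16) and Mapk8ip3 (0.0512) without the Th17 day 2.5 pair. Without the robust fit Lilr4b (0.0754), Scand1 (0.0754), Srsf5 (0.106) and Mapk8ip3 (0.051) did not pass. By limma-voom Lilr4b (0.065), Srsf5 (0.065) and Scand1 (0.0713) did not, and by DESeq2 Lilr4b (0.451) and Ikbke (0.14) did not. Of the 4737 genes with a day effect in Th2 and Th17 cells, 2335 changed one way in both Th1 day pairs and the other way in all 4 Th2 and Th17 day pairs; this difference was not tested.

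The library labelled Th1 WT day 3.5 carried NFATc1/ΔS levels of Gdpd3 and Apobr, the marker genes that separated the genotypes in the Th2 and Th17 libraries and in the Th1 day 2.5 pair. A mislabelled sample needs most markers on the NFATc1/ΔS side, and 100% of the 2 were, but both lie in the same stretch of chromosome 7 and count as a single marker. Shared reads between paralogs are argued against, since the share on unique reads was also 100%. That Th1 cells have no genotype difference left at day 3.5 stays open too, since the pair differed by at least 1 on 0% of the markers. A wrong label and this loss of difference cannot be told apart with so few markers, so the Th1 day 3.5 pair may or may not compare the genotypes.

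The Th1 day changes ran against those of Th2 and Th17 cells. The slope on the day effect of the other cells was -1.11 in the NFATc1/ΔS and -0.25 in the WT libraries. Exchanged day labels within Th1 would turn the slope below 0, but that sign is the pattern itself, so it decides nothing for either genotype. In size the NFATc1/ΔS slope is like those of Th2 and Th17 (0.94 to 1.06), and the WT slope is much smaller. An exchange alone would therefore not give the WT libraries the course of the other cells. Placed along that day effect, both Th1 day 3.5 libraries lay at 0.1. The Th1 day 2.5 libraries lay at 0.35 (WT) and 1.21 (NFATc1/ΔS), so the NFATc1/ΔS library lay farthest out. Each slope rests on 1 pair of libraries. The plate codes of the Th1 libraries of both genotypes run from day 3.5 to day 2.5, where those of Th2 and Th17 run from day 2.5 to day 3.5, and an exchange stays open. Th17 cells in the library labelled Th1 WT day 2.5 implied a median share of 15% of Th17 RNA, yet the abundant Th17 genes Il17f and Ccr6 gave shares of -1 and -1.1% while Acvrl1 gave 68.2%, which argues against such a mixture as the cause. A true difference in the day course of Th1 cells, which the design names, stays open and was not tested.

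Genes with a genotype effect in the 4 Th2 and Th17 pairs partly lay close together on chromosomes. Of 51 tested genes within 10 Mb of Nfatc1, 6 were called (Hdhd2, Epg5, Slc14a1, Setbp1, Tshz1 and Zadh2), more than elsewhere (odds ratio 6.25, one-sided Fisher's exact p = 0.000705), which is in line with variants linked to the edited Nfatc1 locus. An effect of NFATc1 on these genes stays open. For other stretches of the genome, 67 called genes had a called neighbour within 500 kb. Random sets of genes had a median of 58 (permutation p = 0.2), so no general clustering was shown. This count cannot exclude variants in single stretches. The called genes Sbk1 (0.53), Cln3 (0.88), Apobr (3.23) and Gdpd3 (-6.36) lay together on chromosome 7 (126272619 to 126775649). On unique reads 82 genes with a called neighbour were found against 67, or 122.4% as many, with 331 rather than 264 genes called in all. This count grows with the number of genes called and was not beyond random sets, so it does not decide on paralogs sharing reads.

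Other splits of the libraries were counted for each fit. For the genotype effect over 6 pairs, for its difference between cell types and between days, and for the day effect over 6 pairs, the real count was 0, which all 32 exchanges within pairs reach by definition, so they say nothing about chance; the highest other counts were 1, 0, 0 and 2161. The 2161 came from exchanging the days of Th2 and Th17 but not of Th1, which points to the opposite day courses as a structure of the samples. For the 4 Th2 and Th17 pairs the 8 exchanges are too few for a share under 0.05. The genotype effect gave 264 genes (highest other 2; 1 split as large) and the day effect 5022 (highest other 0; 1 split as large). The difference between Th17 and Th2 gave 37 (highest other 341; 2 splits as large) and genotype by day 33 (highest other 566; 2 splits as large). Those high counts came from exchanging both Th17 pairs or both day 3.5 pairs, which turns the common genotype effect into a difference, a structure of the samples. For the cell types, fitted without blocks, 1 of 35 splits, the real one, was as large each time. Th1 against Th2 gave 3071 (highest other 0) and Th1 against Th17 178 (highest other 1). Th2 against Th17 gave 2350 (highest other 1961, the split by day, which points to day as a second structure). Libraries of a cell type differ in genotype and day and are not known to be separate cultures. The splits therefore do not exclude chance.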

How the results depend on the processing

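Exon reads, all alternatives of the 8 Th2 and Th17 libraries, and for the cell types DESeq2, limma-voom, unique reads, the fit without day and leaving out libraries were chosen after seeing the data; the others were planned. No paired analysis was possible because the labels number no replicates; the WT and NFATc1/ΔS pairs are already blocks of the design. Where no reason is given, the cause was not tested.

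RLE size factors, CPM over 1, and exon reads left every count of genes within 1.5 times its main value. The fit without day did so too, where the main count was 0 for the genotype effect in each cell type. The fits without blocks, with a minimum fold change, without both Th2 pairs and without both Th17 pairs covered only the genotype effect over 6 pairs. Its count was 0 in the main fit and in each of these. The minimum fold change makes the test stricter, so its 0 was fixed in advance. These fits do not bear on the 264 genes of the 4 Th2 and Th17 pairs. With RLE the count was 270 for the 4 Th2 and Th17 pairs and 5009 for day in them.

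DESeq2 gave 21 genes for the genotype effect over 6 pairs, 1 in Th1, 10 in Th2, 15 in Th17, 3 for genotype by cell type, 143 for day and 2 for genotype by day, where edgeR gave 0 for each. On the 8 Th2 and Th17 libraries it gave 53 in Th2 (edgeR 128), 94 in Th17 (222), 14 for Th17 minus Th2 (37) and 11 for genotype by day (33), and for Th1 against Th17 1651 (611). limma-voom gave 1 gene over 6 pairs, 16 for Th17 minus Th2 and 12 for genotype by day in the 8 libraries. Without the read filter the counts were 3 over 6 pairs, 5 in Th2, 6 in Th17, 1 for genotype by cell type and 6 for day. In the 8 libraries they were then 630 over the 4 pairs, 357 in Th2, 501 in Th17, 167 for Th17 minus Th2 and 209 for genotype by day. Without the robust fit Th17 minus Th2 gave 17 and genotype by day 9 in the 8 libraries, and on unique reads 61 and 91.

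Fitting fewer samples changed most counts. Without both Th1 pairs the genotype effect over 6 pairs gave 264, and the 4 libraries of a cell type alone gave 211 in Th2 and 343 in Th17. WT libraries alone gave 695 for Th1 against Th2, 0 for Th1 against Th17 and 142 for Th2 against Th17. NFATc1/ΔS libraries alone gave 0 for each. A fit of a single genotype has fewer residual degrees of freedom than the main fit. Both genotypes have equally many, so this does not explain the difference between them.

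Leaving out pairs in turn, the genotype effect over 6 pairs ranged from 0 to 23 (23 without Th1 day 2.5, 8 without Th1 day 3.5). Th1 ranged from 0 to 5133 (12 without day 2.5, 5133 without day 3.5), Th2 from 0 to 126 (119 and 126 without the Th1 pairs) and Th17 from 0 to 218 (215 and 218 without them). Genotype by cell type ranged from 0 to 3668 (89 without Th1 day 2.5, 3668 without Th1 day 3.5), day from 0 to 215 (without Th1 NFATc1/ΔS) and genotype by day from 0 to 7 (without Th1 day 2.5). Where 1 Th1 pair remains, it is assumed to vary like the other cell types.

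In the 8 libraries the genotype effect over 4 pairs ranged from 124 (without Th2 day 2.5 or Th17 day 3.5) to 239, Th2 from 129 to 180, and Th17 from 95 (without Th17 day 3.5) to 459 (without Th2 day 3.5; 379 without Th2 day 2.5, 120 without Th17 day 2.5). Th17 minus Th2 ranged from 27 to 107 (107 and 82 without Th2 day 2.5 and 3.5). Day ranged from 3748 to 4345, and genotype by day from 20 (without Th17 day 2.5) to 138 (without Th2 day 2.5; 64 without Th2 day 3.5, 99 without Th17 day 3.5).

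Leaving out libraries in turn, Th1 against Th2 ranged from 2042 (without Th2 WT day 3.5) to 4206; without Th2 NFATc1/ΔS day 2.5 or 3.5 it gave 2310 or 2344. Th1 against Th17 ranged from 166 (without Th17 WT day 3.5) to 928 (without Th1 NFATc1/ΔS day 2.5). It gave 172 without Th17 NFATc1/ΔS day 3.5, 184 without either Th17 day 2.5 library, 216 and 393 without the Th1 WT and NFATc1/ΔS day 3.5 libraries, and 353 and 328 without the Th2 ones. Th2 against Th17 ranged from 719 (without Th2 WT day 3.5) to 2954 (without Th1 NFATc1/ΔS day 2.5). It gave 853 without Th2 WT day 2.5, 784 without Th2 NFATc1/ΔS day 3.5, 886 and 786 without the Th17 WT libraries, 755 without Th17 NFATc1/ΔS day 3.5 and 1032 without Th2 NFATc1/ΔS day 2.5.

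Of the list tests, the preset correlation called 13 lists over 6 pairs, 4 in Th1, 14 in Th2, 8 in Th17 and 7 for day, and in the 8 libraries 14 over 4 pairs, 14 in Th2, 10 in Th17 and 5 for day. The estimated correlation called 0 lists in each of these 9 comparisons. On simulated data it gave a raised list a much larger p, but the simulated genes were drawn independently of each other. The simulation therefore cannot tell which setting suits correlated lists, such as cell cycle (estimate 0.507 over 6 pairs) and mitochondrially encoded genes (0.772). Without members shared by lineage lists day in the 8 libraries gave 3, and the other counts stayed within 1.5 times. Leaving out pairs, the counts ranged from 10 to 14 over 6 pairs, 3 to 7 in Th1 (7 without day 3.5), 9 to 16 in Th2 (9 without either Th2 pair), 5 to 10 in Th17 (5 without Th17 day 3.5) and 5 to 7 for day. In the 8 libraries they ranged from 13 to 16 over 4 pairs, 10 to 16 in Th2, 8 to 10 in Th17 and 4 to 5 for day.

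Some directions reversed with the pair left out. In Th1, Ifng ranged from -0.30 to 1.79 and Il13 from -0.33 to 1.65, below 0 without the Th1 day 2.5 pair and highest without the day 3.5 pair. The cell cycle list in Th1 pointed down without the day 2.5 pair (camera adjusted p = 0.0109) and up without the day 3.5 pair (2.23e-05). Il2 in Th17, in the 8 libraries, ranged from -0.93 without the Th17 day 2.5 pair to 0.51 without the day 3.5 pair. Each of these then rests on the remaining pair of its cell type alone. For named genes over the 4 Th2 and Th17 pairs, 396 of 418 values under the alternatives kept their side of the threshold without a clear reversal. The other 22 were no longer past it. Over 6 pairs 448 of 475 values were kept in this sense and 27 came to pass. In Th17 within the 8 libraries 335 of 357 were kept, and in Th2 337 of 359. A change of sign was not counted as a reversal where neither fit passed and either value lay within its standard error. Such changes occurred, for example for Il2 over the 4 pairs (-0.39 to 0.48) and Ifng over 6 pairs (-0.29 to 0.51). For genes with few reads depth limits what can be tested. Il17f over 6 pairs was left out by the read filter because its reads lay mainly in the Th17 libraries.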

Other observations

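Xist ran from 120.9 to 255.3 CPM in all 12 libraries, and no library had more than 5 reads on the Y-linked genes. Intron reads made up 3.98 and 4.16% of the Th2 and Th17 NFATc1/ΔS libraries at day 3.5, against 2.93 and 3.28% of their WT partners. The library labelled Th1 WT day 2.5 had a correlation across genes of 0.977 with the library labelled Th17 WT day 3.5, and the Th1 day 3.5 pair one of 0.994; genes are not independent replicates. The TMM factors ran from 0.866 to 1.10.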
